A study of Homo sapiens with 2 samples.

How the data were processed

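Total RNA of MDA-MB-231 cells was sequenced in 1 library of control cells and 1 library of FBXO44 knockdown cells, and each library was assigned to its group from its treatment label. The deposited values are RPKM (reads normalised to the length of the gene model and to the reads of the library), which the authors gave for 26364 gene symbols in both libraries. Per the submitters' processing notes, STAR and the hg19 build were used. The role and version of STAR, the read counter, the annotation behind the gene lengths and the use of strand are not given in the sources used here. Reads of near-identical genes (AKR1C, HLA class I, metallothionein, histone, HSPA1A and HSPA1B, and MAGEA genes) and of overlapping or antisense genes are therefore uncertain in their assignment.

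Depth was worked out from the values. An RPKM of whole reads is a whole multiple of what 1 read is worth in that gene, so the ratio of the libraries' depths was taken from 418 genes with equal reads below 5 RPKM, and the absolute depth from single-exon gene lengths, on which 102 of 502 such genes coincided. This gave about 33916200 reads behind the control values and about 33092400 reads behind the knockdown values, a ratio of 1.02. With these depths 17778 of the 17781 genes above 0 (99.98%) came out as whole reads. With a depth wrong by 0.07% only 12 of 300 drawn genes did. The reads of a gene are the smallest whole pair that fits its values, so they are lower bounds. A read in a gene of 1 kb was worth 0.0295 RPKM in the control library and 0.0302 RPKM in the knockdown library. Exact 95% Clopper-Pearson intervals of the ratio of reads cover counting error only. They were computed from these lower bounds, so they can be wider than the true reads would give.

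Fold changes were computed as log2((knockdown RPKM + 1)/(control RPKM + 1)), with a pseudocount of 1 RPKM, which understates the difference of low genes. Ratios quoted as "fold" are ratios of the RPKM values without a pseudocount. Genes at 1 RPKM or more in at least 1 library were kept (11651 genes). With 1 library per group no test across genes was possible, so genes were counted by size: a log2 fold of 1 or more (2-fold) in either direction. The same size applied to lists was 1.5-fold. Of 35 gene lists fixed before the data were examined, 28 had at least 8 members at 1 RPKM or more. The median of each was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list at or below 2.5 or at or above 97.5 was called apart from matched lists, as a description of these libraries; chance alone would place 1.4 of 28 lists there. The genes named are FBXO44, the 14 highest and 14 lowest folds among genes at 5 RPKM or more in at least 1 library, up to 4 members of each list with the largest folds, and the 5 most abundant genes. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

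Words of 7 bases were searched in the longest 3′ UTR of at least 50 bases of each gene, taken from the GENCODE 29 basic set on GRCh38 and matched by gene symbol, older symbols included. This covered 10613 of the 11651 genes (91.1%). Folds were adjusted for 3′ UTR length, GC content and expression level by regression with quadratic terms, and the 16169 words present in at least 50 genes were ranked by the mean adjusted fold relative to its spread over genes. Genes with GACCTGA were also set against genes without it in the same of 5 bins of each property, and the scan was repeated on 100 shuffles of the adjusted folds over genes. Intervals of medians came from 2000 bootstrap draws over genes, which are not independent replicates. The scan was exploratory: it was first run on genes at 5 RPKM or more and then extended to 1 RPKM, and the 4 words followed further were chosen after their ranks were seen. Neighbouring genes were taken in RefSeq order.

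The steps were tested on simulated data for the knockdown against control comparison, with reads drawn for 17778 genes at the depths of these libraries. The right ratio of reads was recovered for 100% of genes and the exact reads for 85.7%. The simulated genes were given the smallest lengths and reads that fit the data, and such lengths also set the simulated depth. The 85.7% can therefore overstate how often the real reads are exact. Genes set 3-fold higher were called in 98% of cases and genes set 3-fold lower in 83.7%, while 0% of genes set 1.5-fold higher or lower were called. Counting error alone called 19 of 11232 unchanged genes. Of 200 random lists of 40 unchanged genes 14 fell outside the limits, and 50 of 50 lists raised 1.25-fold were called higher. Simulated unchanged genes varied by counting error only, with an SD of log2 fold of 0.106, against 0.595 among the genes kept in the data. The share of raised lists that were called therefore does not carry over to the real lists. Alternatives covered the pseudocount, the filter, 4 other scalings or centrings, a trend on mean level, the size rule, the matching and the membership of lists, and the removal of genes with the 4 words, of genes without a searched 3′ UTR, or of both, which were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Transcripts of repeated elements and mitochondrially encoded genes, of which the table lists 0, were not analysed here.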

Results

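RNA sequencing was carried out on MDA-MB-231, an established human breast cancer cell line of the triple-negative, mesenchymal type. One library came from control cells and the other from cells depleted of FBXO44, an F-box protein that recognises substrates for an SCF ubiquitin ligase. How the knockdown was made is not stated in the labels. The values rested on about 33916200 reads in the control library and about 33092400 reads in the knockdown library, with a median of at least 1071 and 1010 reads per gene kept. The comparison asks which transcripts differ in level when FBXO44, studied for its part in silencing repeated elements in cancer cells, is depleted. With 1 library per group there was no replicate check, and each difference describes these 2 libraries.

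FBXO44 was lower in the knockdown library, at a ratio to the control library of 0.167 (95% counting interval 0.0984 to 0.269), with 1.03 RPKM and at least 123 reads in the control library against 0.171 RPKM and at least 20 reads. The direction matched the labels. The gene sits near the filter, so its log2 fold was only -0.79 with the pseudocount of 1 RPKM and -2.06 with 0.1 RPKM. Its chromosomal neighbours were higher: FBXO2 went from 1.43 to 10.5 RPKM (7.37-fold) and FBXO6 from 2.34 to 6.13 RPKM (2.62-fold). Both encode F-box proteins that bind glycoproteins.

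NF-kB target and epithelial gene lists were higher in the knockdown library, and mitotic, DNA replication and ribosomal protein lists were lower. Of 11651 genes, 496 (4.26%) were at least 2-fold higher and 467 (4.01%) at least 2-fold lower. At 4-fold the counts were 55 and 25. At 1.5-fold, the size used for lists, 1481 of the 11651 genes were higher and 1643 lower, against which the counts within lists are to be read. The read intervals of 486 of the higher and 449 of the lower genes excluded a ratio of 1. Across these genes, which are not independent replicates, Pearson's r between the libraries was 0.948.

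**Figure D1:**
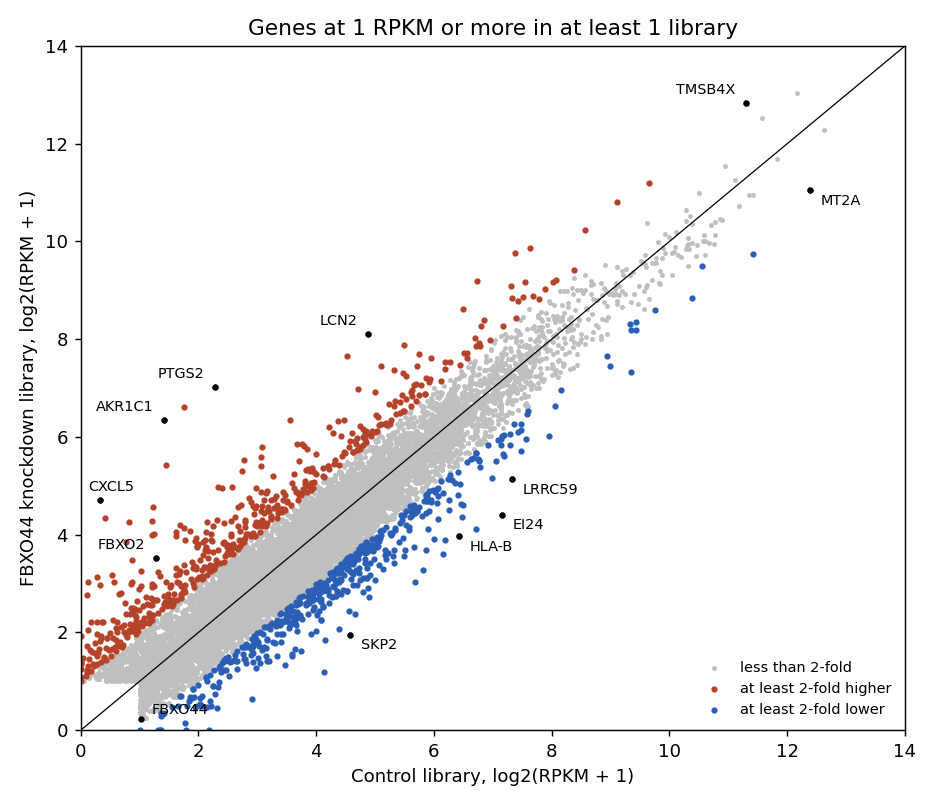
Each point is a gene at 1 RPKM or more in at least 1 library, with its level in the control library on the x axis and in the FBXO44 knockdown library on the y axis, both as log2(RPKM + 1). Red points (496) are at least 2-fold higher, blue points (467) at least 2-fold lower, black points are named genes, and the line marks equal levels.

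The genes with the highest folds included enzymes of carbonyl and steroid metabolism and secreted products of epithelia and inflammation. AKR1C1, an aldo-keto reductase, stood at 1.67 RPKM in the control library and 80.0 RPKM in the knockdown library. AKR1B10, of the same enzyme family, went from 0.776 to 18.1 RPKM, and DHRS9, a short-chain dehydrogenase, from 0.0903 to 7.18 RPKM. PTGS2, the inducible cyclooxygenase, went from 3.87 to 128 RPKM (33.2-fold, interval 30.6 to 36.1). The protease inhibitors PI3 and SLPI were 40.7-fold and 24.2-fold higher. LCN2, an iron-binding lipocalin, went from 28.4 to 273 RPKM. C1S, DUSP13, SELPLG and LRG1 also belonged to this set, as did the cytokines CXCL5 and IL23A, which were 102-fold and 18.9-fold higher.

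Among the genes with the lowest folds, SKP2, the F-box protein that targets the cell cycle inhibitor p27, was 7.93-fold lower (22.8 to 2.87 RPKM, interval 6.50 to 9.75). EI24 was 6.99-fold lower (141 to 20.2 RPKM), the sialomucin PODXL 6.97-fold, the matricellular growth factor CTGF 6.42-fold and the histidyl-tRNA synthetase HARS 6.30-fold. RHOBTB3, AIDA, ANP32E and LRRC59 were between 6.49-fold and 4.67-fold lower. HLA-B went from 84.6 to 14.6 RPKM and the metallothionein MT1A from 19.9 to 3.20 RPKM, both with near-identical relatives. KRTAP2-3 had at least 40 and 3 reads (13.0-fold lower, interval 4.14 to 65.7) and SNORD78 at least 12 and 1 reads (11.7-fold lower, interval 1.73 to 501). These are the smallest reads that fit, so the true reads can be more and the intervals narrower. The 5 most abundant genes also differed: FTL (4606 to 8455 RPKM), TMSB4X (2513 to 7292 RPKM) and S100A6 (3049 to 5860 RPKM) were higher, ACTB (6346 to 4972 RPKM) and MT2A (5335 to 2116 RPKM) lower.

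Almost all mitotic and DNA replication genes had a fold below 0, many of them by less than 1.5-fold, and G1/S regulators were lower in part. Of 61 mitotic genes 60 had a fold below 0 and 38 were at least 1.5-fold lower, with 0 at least 1.5-fold higher (median log2 fold -0.67, percentile 0). CDC20, the activator of the anaphase-promoting complex, went from 144 to 49.0 RPKM, the phosphatase CDC25B from 59.6 to 21.3 RPKM and topoisomerase TOP2A from 86.0 to 31.7 RPKM. Of 56 DNA replication genes 30 were at least 1.5-fold lower and 0 higher (median -0.61, percentile 0), including TOPBP1 (3.83-fold), the ligase LIG1 (2.67-fold) and the helicase subunit MCM2 (2.56-fold). Among 26 regulators of the G1/S transition 12 were lower and 1 higher (median -0.55, percentile 0), with SKP2, CDC25A (2.74-fold), E2F7 (2.38-fold) and CDK4 (2.14-fold) the lowest. Of 56 DNA damage response and repair genes 17 were lower and 1 higher (median -0.39, percentile 0), among them the nuclease EXO1 (2.85-fold) and the recombination factor RAD54L (2.93-fold). Of 20 measured replication-dependent histones 6 were lower and 2 higher (median -0.35, percentile 0.42); 44 of 64 lay below 1 RPKM and their mRNAs carry no poly(A) tail. With genes lacking a searched 3′ UTR left out, the histone median was 0.09 (percentile 75.7), so this call rests on the genes not searched.

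Ribosomal protein genes were lower as a group. Of 76 cytosolic ribosomal protein genes 73 had a fold below 0 and 24 were at least 1.5-fold lower (median -0.49, percentile 0), led by RPL35 (2752 to 859 RPKM), RPSA (690 to 290 RPKM) and RPL13A (177 to 75.5 RPKM). Of 88 small nucleolar RNA genes 49 were lower and 5 higher (median -0.72, percentile 0; -0.37 without a filter). The smallest reads that fit them were few, as SNORD101 with at least 9 and 1 (8.78-fold lower, interval 1.22 to 385), and 283 of 371 snoRNA genes lay below 1 RPKM. Of 6 small structural RNAs without poly(A), some of them also snoRNAs, 4 were lower and 1 higher, among them RPPH1, the RNA of ribonuclease P (2.24-fold lower). Of 369 genes with a ZNF symbol 25 were lower and 10 higher. Each is a smaller share than among all 11651 genes, of which 1643 were lower and 1481 higher. The list was called lower only by a small shift of the median (-0.11, percentile 0.64), which kept its call in 11 of 14 alternatives. ZNF721 was 3.78-fold lower and ZNF165 3.70-fold higher.

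NF-kB targets and inflammatory cytokines were higher. Of 31 members 16 were at least 1.5-fold higher and 2 lower (median 0.70, percentile 100). Besides PTGS2 and CXCL5, the chemokine CCL20 was 7.55-fold higher (4.03 to 30.4 RPKM) and the cytokine IL24 6.43-fold higher (7.32 to 47.0 RPKM). Of 35 apoptosis regulators 8 were higher and 4 lower (median 0.29, above the upper limit of matched lists; 0.16 without a filter, with the same call). BIK and CASP4, which promote cell death or inflammation, were 3.58-fold and 2.10-fold higher, and BCL2A1, which opposes cell death, was 5.03-fold higher.

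Epithelial and luminal breast genes were also higher, with 13 of 24 at least 1.5-fold higher and 1 lower (median 0.66, percentile 100). The call was kept in 14 of 14 alternatives, but the median ranged from 0.14 without a filter to 1.03 with a filter at 5 RPKM. The mucin MUC1 went from 5.87 to 45.3 RPKM, the secreted AGR2 from 21.1 to 80.3 RPKM and the epithelial transcription factor ELF3 from 1.49 to 8.40 RPKM. Mesenchymal genes went both ways, 11 of 29 higher and 8 lower (median 0.09, percentile 83.2; -0.21 with a filter at 5 RPKM, percentile 8.41). Fibronectin FN1 went from 19.7 to 79.0 RPKM, while the receptor kinase AXL and the matrix protein TNC were 3.87-fold and 3.69-fold lower. Of 25 cholesterol synthesis genes 6 were higher and 0 lower (median 0.24, percentile 98.5), among them TM7SF2 (2.98-fold) and INSIG1 (2.66-fold); this call held in 12 of 14 alternatives.

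Interferon-stimulated genes did not stand apart from matched lists. Of 60 members 6 were at least 1.5-fold higher and 16 lower (median -0.11, percentile 21.0; 0.04 without genes that hold the words described further on or were not searched). The antiviral genes IFIT1 and IFIT2 were 2.88-fold and 2.93-fold lower, and MX1 and IFI35 3.19-fold and 2.30-fold higher. Genes of nucleic acid sensing and interferon induction had 5 of 19 members higher and 2 lower (median 0.22, percentile 97.8), a call kept in only 4 of 14 alternatives. IRF7 was 2.28-fold and TICAM1 2.15-fold higher, and TLR3, a sensor of double-stranded RNA, was 4.31-fold lower. Among 21 genes of MHC class I presentation 3 were higher and 4 lower (median -0.05, percentile 45.9), with HLA-C 3.16-fold and CANX 2.03-fold lower. Of 6 measured interferons and receptors IFNGR1 was 4.13-fold higher and IL10RB 1.93-fold lower.

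Chromatin lists that bear on the silencing of repeated elements did not stand apart from matched lists when all genes were used. Of 33 H3K9 methylation and heterochromatin factors 11 were at least 1.5-fold lower and 1 higher (median -0.20, percentile 7.60), and 28 had a fold below 0. No other setting fixed before the data were seen gave a higher percentile for this list. With a filter at 5 RPKM it was 2.515 (median -0.29), just above the limit of 2.5. Without genes that hold the 3′ UTR words described further on, the H3K9 list was called lower (median -0.32, percentile 0.44). The members with the lowest folds also have parts in proliferating cells: LMNB1 (2.39-fold), the chromatin assembly factor CHAF1A (2.06-fold), the methyltransferase SUV39H2 (2.02-fold) and CBX3 (1.81-fold). Among 30 DNA methylation and Polycomb factors 4 were lower and 0 higher (median -0.11, percentile 27.3), DNMT1 by 1.81-fold. Genes derived from endogenous retroviruses and transposons had 3 of 15 lower and 0 higher, with a median of 0.03, a mean of -0.18 and PEG10 2.08-fold lower (percentile 64.5). Of 6 measured cancer-testis antigens SSX1 was 2.55-fold higher, and of 8 genes with a MAGE symbol MAGEH1 was 1.93-fold lower (median -0.11, percentile 30.5). Long intergenic non-coding RNA genes had 18 of 71 higher and 6 lower (median 0.15, percentile 97.9), LINC00880 by 7.83-fold, a call kept in 5 of 12 alternatives.

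The remaining lists had medians inside the range of matched lists and some members with large folds. Of 35 p53 targets 6 were higher, GDF15 by 6.98-fold, and 5 lower, CCNG1 by 3.48-fold (median 0.04, percentile 82.0). Unfolded protein and integrated stress response genes had 10 of 33 higher and 3 lower (median 0.06, mean 0.23, percentile 80.6). Of these, CTH was 4.56-fold and the cystine transporter SLC7A11 4.31-fold higher. Glycolysis and hypoxia genes had a median of -0.04 and a mean of 0.03 (percentile 44.3), with the glucose transporter SLC2A3 3.70-fold higher and PFKFB3 3.07-fold lower. For 72 nuclear genes of oxidative phosphorylation the median was 0.00 and the mean -0.03 (percentile 59.1), UQCRFS1 being 2.23-fold lower. Immediate-early genes had a median of 0.08 and a mean of -0.03 (percentile 79.5), with CTGF and CYR61 lower and IER3 2.90-fold higher. Among 16 heat shock genes (median 0.01, percentile 63.1) HSPB1 was 2.23-fold higher. Cullin-RING ligase components had a median of -0.08 (percentile 34.3), and of 27 members 2, FBXO2 and FBXO6, were at least 1.5-fold higher and 3 lower, among them SKP2 and CUL5 (2.34-fold).

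Most markers of other cell types lay below 1 RPKM. Of 26 leukocyte markers 6 reached it and 5 had a fold above 0, among them CD68, a lysosomal glycoprotein (158 to 542 RPKM), LCP1 (30.1 to 50.7 RPKM) and LYZ (0.428 to 1.87 RPKM). Of 13 endothelial markers 4 reached it and all 4 had a fold above 0, EGFL7 (11.3 to 37.0 RPKM), ESAM (62.1 to 72.7 RPKM), ROBO4 and PECAM1. Of 17 kidney and neural markers 4 reached it and went both ways, SIX2 from 3.83 to 8.22 RPKM and TUBB3 from 73.6 to 60.9 RPKM.

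**Figure D2:**
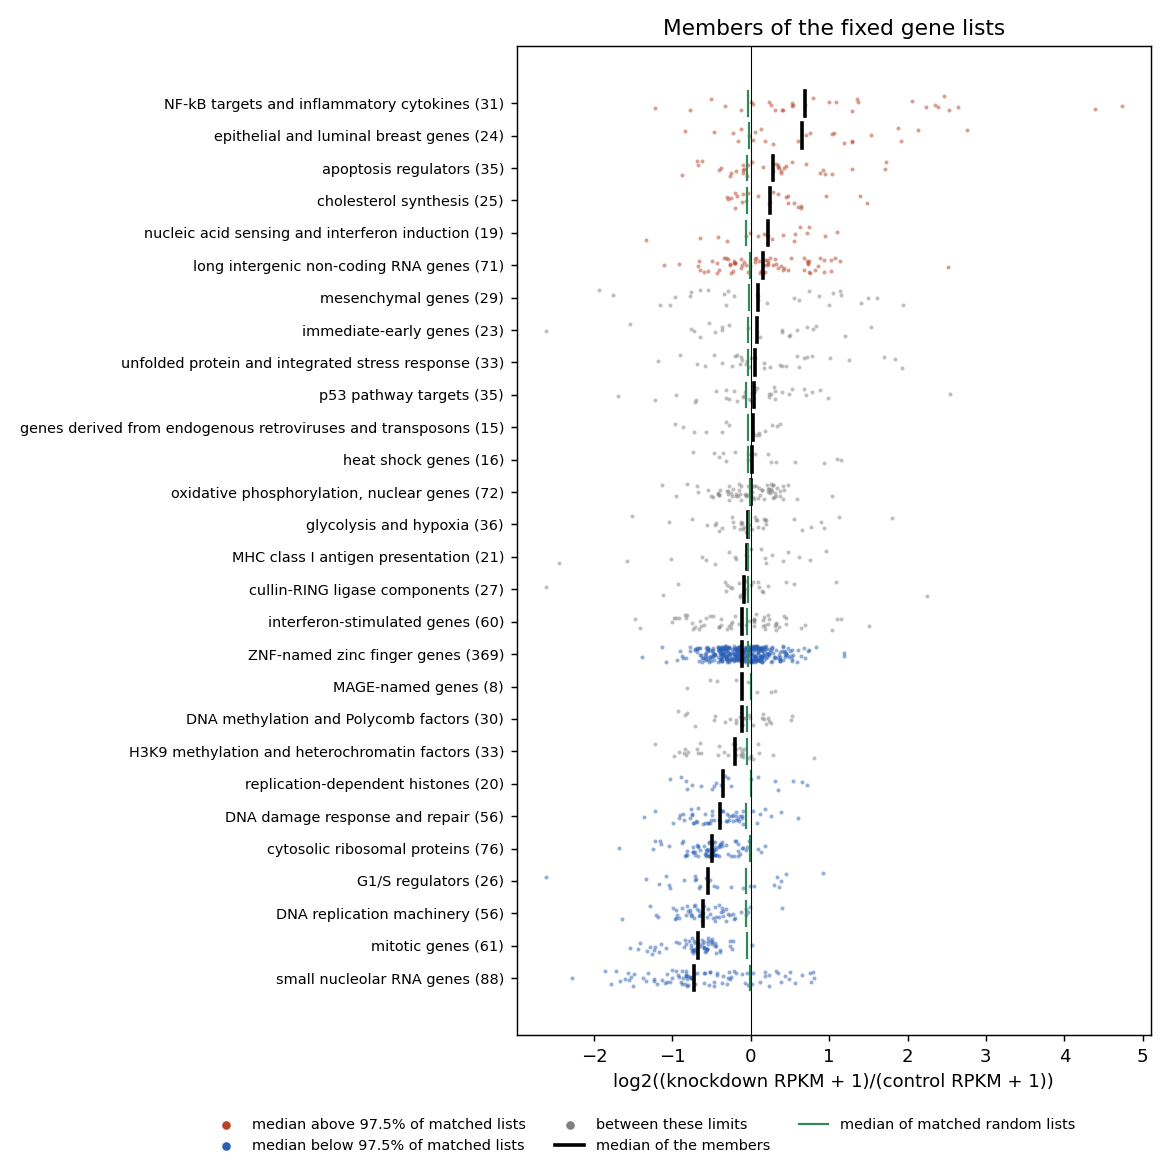
Each point is a gene of a fixed list at 1 RPKM or more in at least 1 library, placed by its log2((knockdown RPKM + 1)/(control RPKM + 1)), with the number of members in brackets. Black bars are list medians and green bars the medians of matched random lists. The 6 lists in red and the 8 in blue lie outside the limits of matched lists, and the others, in grey, do not.

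Lower genes shared short words in their 3′ UTRs. Of 16169 words of 7 bases, GACCTGA and ACCTGAA had the lowest ranks (1 and 2) after adjustment for 3′ UTR length, GC content and level. Of 403 searched genes at least 2-fold lower, 188 (46.7%) held either word, against 10.8% of 453 searched genes at least 2-fold higher and 18.2% of genes that differed less. Of the 14 genes with the lowest folds 13 were searched and 7 held either word, RHOBTB3 and HARS as the 8-base GACCTGAA and SKP2 not at all. LIG1, TLR3, AXL, CANX and CUL5 also held GACCTGAA, and HLA-B, HLA-C, IFIT1, IFIT2, TOPBP1, TOP2A and RPL35 a 7-base word. For these words, picked for their ranks, the median adjusted log2 fold was -0.27 for 303 genes with GACCTGAA, -0.18 for 711 genes with GACCTGA but not GACCTGAA and 0.02 for 6873 genes without the core ACCTGA. FBXO44 itself holds GACCTGAA at the end of the stretch CGAAAGGTCTTGACCTGAA, which lies at 11661463 to 11661481 on chromosome 1 (GRCh38), in the 3′ UTR part of the last exon of 4 of its 6 basic transcripts. The same stretch holds GAAAGGT, the reverse complement of ACCTTTC. ACCTTTC ranked 8 and CCTTTCA, which overlaps it, ranked 7 of the 16169 words, and 433 genes with the 8-base ACCTTTCA had a median adjusted log2 fold of -0.12 (interval -0.17 to -0.08). Without genes that hold these words or ACCTTTC or CCTTTCA, 7911 genes were left, of which 401 were at least 2-fold higher and 212 lower. With genes not searched also left out, the counts were 358 and 148 of 6873 genes. The words were picked for the low folds of the genes that hold them, so a fall in the lower count was bound to follow.

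**Figure D3:**
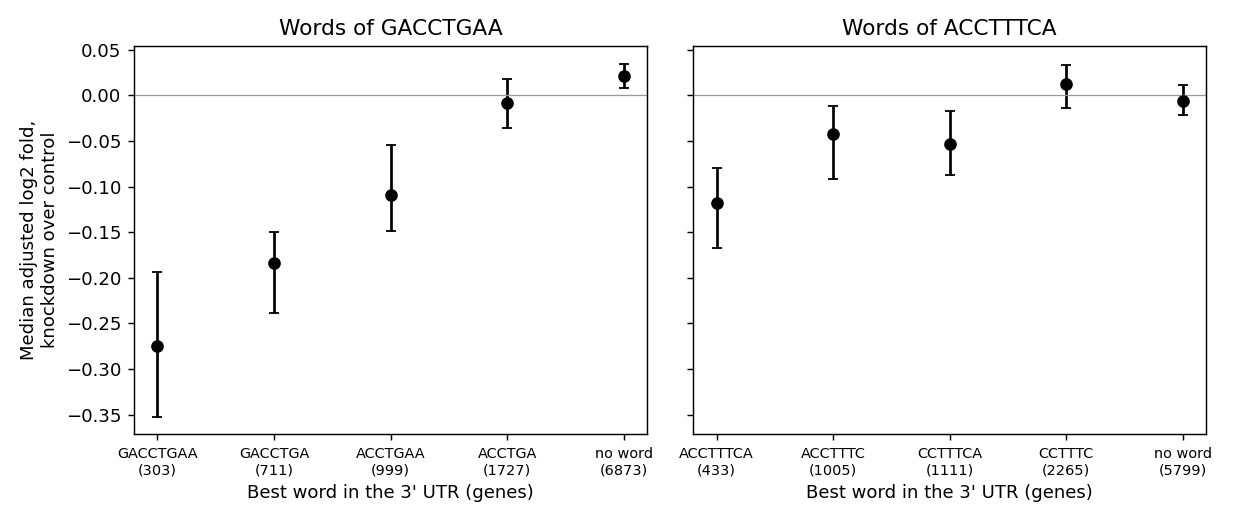
Median log2 fold of knockdown over control, adjusted for 3′ UTR length, GC content and level (y axis), of genes grouped by the longest word of GACCTGAA (left) or of ACCTTTCA (right) in their 3′ UTR, with gene numbers in brackets. Bars are 95% bootstrap intervals over genes; the 303 genes with GACCTGAA lie at -0.27 and the 433 genes with ACCTTTCA at -0.12.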

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

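Leaving out genes with the 4 words, genes without a searched 3′ UTR, or both, was chosen after seeing the data; all other settings were fixed before. No paired analysis was possible because each group had 1 library, and no library could be left out. Of 384 list comparisons 358 kept their call; the mitotic, replication, G1/S, DNA damage, ribosomal protein, snoRNA, NF-kB, epithelial and apoptosis lists kept theirs in every alternative run. Medians of lists without a call crossed 0 in places, as the mesenchymal list (-0.21 with a filter at 5 RPKM), MAGE genes (0.03 without a filter) and interferon-stimulated genes (0.04 without word genes and unsearched genes). The log2 fold of FBXO44 was -2.06 with a pseudocount of 0.1 RPKM, -1.19 with 0.5 RPKM and -1.27 on the TPM scale. Counts of higher and lower genes were 801 and 758 with a pseudocount of 0.1 RPKM, 1481 and 1643 at 1.5-fold, and 128 and 80 at 3-fold. The list of nucleic acid sensing lost its call at a median of 0.22 with both other pseudocounts, without matching, without shared members and without unsearched genes, 0.24 with a filter at 5 RPKM, 0.23 on the TPM scale and 0.25 with the trend removed. Long intergenic RNA genes lost theirs at 0.18 with a pseudocount of 0.1 RPKM, 0.0190 without a filter, 0.18 with a filter at 5 RPKM, 0.18 with a trimmed mean, 0.20 at equal upper quartiles and 0.11 with the trend removed. The ZNF list lost its call at -0.17 with a filter at 5 RPKM. Without word genes 212 genes were lower; nucleic acid sensing (0.21), cholesterol synthesis (0.26), ZNF (-0.0432) and long intergenic RNA genes (0.15) lost their calls, and the H3K9 list gained one (-0.32). Without word genes and unsearched genes 148 were lower, with the lists at 0.21, 0.26, -0.0214 for ZNF genes and -0.32. The histone median turned to 0.0948 without unsearched genes, where fewer histones are left, and to 0.00285 without both. The other causes were not tested. The share of higher among all genes past 2-fold was 51.5%, 48.9% with a filter at 5 RPKM, 47.4% at 1.5-fold, 61.5% at 3-fold, 60.4% at equal upper quartiles, 65.4% without word genes and 70.8% without word genes and unsearched genes. The shares without word genes were bound to rise, since the words were picked for the low folds of the genes that hold them. Depth limits the snoRNA, histone and low FBXO44 values.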

Other observations

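The scan of gene families, the family members named here, the tests on the word GACCTGA, the scaling test and the test of reads shared between FBXO44 and its neighbours were chosen after the result was seen; the tests of words in replication genes and of the neighbourhood were set before.

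Gene families grouped by the start of their symbol showed further differences. Of 185 families of at least 8 members, 16 fell at or below the lower percentile limit among matched random lists and 19 at or above the upper one, where chance gives 4.6 each. Counted by full symbol, the small nucleolar RNA host genes (SNHG) were at least 1.5-fold lower in 12 of 17 and higher in 0 (median log2 fold -0.63). Proteasome beta subunits (PSMB) were higher in 5 of 10 and lower in 0 (median 0.57), and matrix metalloproteinases (MMP) higher in 6 of 9 and lower in 0 (median 0.84). Tetraspanins (TSPAN) were higher in 5 of 14 and lower in 1 (median 0.45). FK506-binding prolyl isomerases (FKBP) were lower in 6 of 11 and higher in 1 (median -0.65), with FKBP14 at -1.82 and FKBP2 at 1.09.

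Of 7 cystatins at 1 RPKM or more, 6 were at least 1.5-fold higher and 0 lower, too few for a percentile: CST1 went from 44.0 to 233.8 RPKM, CST2 from 10.7 to 80.6, CST4 from 25.3 to 124.8 and CST7 from 6.91 to 30.1. All 6 metallothioneins at 1 RPKM or more, which bind zinc and copper, were at least 1.5-fold lower, again too few for a percentile: beside MT1A and MT2A, MT1E went from 647 to 160 RPKM, MT1F from 21.2 to 8.01 and MT1X from 458 to 254. Both families hold near-identical members that can share reads.

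Genes with GACCTGA in the 3′ UTR were lower in the knockdown library, and repression through the seed of a short duplex matching FBXO44 is a candidate explanation that stays open: genes with the 8-base GACCTGAA differed in median by -0.27 from those with only the 6-base core (interval -0.35 to -0.18), but its words were picked for their low ranks, so this decides nothing. Against genes without the word matched on 3′ UTR length, GC content and expression level, the median difference was -0.24 (interval -0.28 to -0.20). Unmatched, the difference of medians was also -0.24, so matching left it nearly unchanged. The word was picked for its low rank after adjustment for the same 3 properties, so this does not decide whether they are the whole cause. Genes with the reverse complement TCAGGTC lay 0.21 higher in mean adjusted log2 fold. A word picked as the lowest lies below most others, so base composition is not decided either. Chance among the 16169 words is argued against by a z of -12.7, where the lowest z of any word in 100 shuffles of the folds over genes was -4.55. Among genes without the 4 words in the 3′ UTR, those with GACCTGA in the coding sequence were lower too, by a difference of medians of -0.19 that was not adjusted. The sequence of the reagent is not in the labels, and no second reagent was analysed. ACCTTTC and CCTTTCA, at ranks 8 and 7, were also picked for their ranks, so their low folds decide nothing. GACCTGA and the reverse complement of ACCTTTC lie in the same 19-base stretch of FBXO44, which goes with a duplex. The ranks did not fix that shared place, but how often such words share a stretch by chance was not tested. Loss of FBXO44 acting on these genes stays open as untested.

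DNA replication and mitotic genes were lower in the knockdown library. Words in their own 3′ UTRs are argued against as the whole cause, since the 90 of 116 searched members with none of the 4 words had a median log2 fold of -0.60, at percentile 0 among matched genes without the words. Scaling of the libraries is argued against, since the median log2 fold over genes at 1 RPKM or more in both libraries was only -0.05. Centring on it left the members at a median of -0.57 (interval -0.65 to -0.53). A shift that small could not have removed the difference, so the centring itself adds no separate evidence. Slower proliferation, whether from loss of FBXO44 or from lower genes that carry the words, could give this pattern and was not tested.

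FBXO2 and FBXO6 were higher beside the lower FBXO44. Reads of FBXO44 counted for these neighbours are argued against, because the pair gained at least 705 reads where FBXO44 lost at least 103 and at most 206, if its gene model is no longer than its span of 8953 bases (GRCh38, introns included), a difference of at least 499. A difference of the whole neighbourhood is argued against by the 5 nearest expressed genes on each side, whose median log2 fold lay at percentile 15.4 of 11247 such windows; MAD2L2, next to FBXO6 and chosen after its values were seen, stood at 25.9 and 28.6 RPKM. A response of FBXO2 and FBXO6 to loss of FBXO44 may remain, as an untested hypothesis.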
